A study of Mus musculus and Homo sapiens with 17 samples.

How the data were processed

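RNA was measured in 17 libraries prepared with a stranded kit that selects poly(A) RNA, per the labels' protocols. The mouse RNA came from whole frozen tissue sections, so all cell types of a section entered it, although the labels name keratinocytes as the cell type. The A431 RNA came from tumour cells recovered from xenografts after depletion of mouse cells. The values used are the deposited counts per gene, whole numbers without normalization, as 1 table for mouse and 1 for A431. Per the submitters' processing notes HISAT2, StringTie and DESeq were used with the builds mm10 and hg38, with no versions. The counting rule, the strand setting, the treatment of reads that match several places and the annotation are not given in the sources used here. Values of genes that overlap, lie antisense or have near-identical copies are therefore uncertain. This holds for the keratin 6, small proline-rich, late cornified envelope, tryptase, MHC, IFIT and immunoglobulin families and for pseudogenes.

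The mouse table held 55988 features, of which 1456 had no gene name, and that of A431 held 58958, of which 223 had none. Features without a name held 0.115 to 0.496% of the counts of a mouse library and 0.190 to 0.211% of those of an A431 library and were left out of library sizes and tests. Totals over all features were 34.4 to 47.9 M in mouse and 41.2 to 53.5 M in A431. As the upper limit for a gene at 0 counts, 3 counts per library were taken, which covers counting error only. Libraries were grouped by the labels, and no column was left out. Replicates were compared by Pearson's r of log2 CPM across genes, which was 0.896 to 0.983 in mouse and 0.990 to 0.993 in A431. Chi-square per degree of freedom was 15.4 to 267 in mouse and 3.56 to 14.0 in A431, far above sampling noise, and no library was found to be deposited more than once. Genes are not independent replicates, so these values describe the libraries.

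The 11 mouse libraries were fitted together with 4 groups, which then share 1 estimate of the spread, and the 6 A431 libraries in a fit of their own. edgeR 4.0.16 in R 4.3.3 was used with its default filter on low counts, TMM normalization and the quasi-likelihood test, two-sided. This left 22371 mouse genes and 18090 A431 genes. Normalization factors were 0.816 to 1.24 and 0.976 to 1.02. All adjusted p-values of genes are from this test with Benjamini-Hochberg adjustment within a comparison, at a threshold of 0.05, unless DESeq2 1.42.0 is named. Fold values are the ratios that correspond to the fitted log2 fold changes, and levels are counts per 1e6 counts (CPM) of the library size scaled by the normalization factor, given as mean ± SD over the libraries of a group. The comparisons were those the labels allow between lesions or genotypes, 4 in mouse and 1 in A431. Tests on simulated counts, with 200 genes changed among those of each comparison, found 8.42% of 2-fold and 41.3% of 4-fold changes in KO SCC against WT SCC. In the A431 comparison 77.3% of 2-fold and 100% of 4-fold changes were found. Genes left unchanged made up 0 and 7.14% of the calls there. The adjustment is stricter where fewer genes change, so the shares found may be lower than in data with more changed genes.

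Before the data were examined, 40 gene lists (pathways and cell type markers), the tests, the alternatives and a rule for the genes to be named were fixed. Lists with at least 5 tested members were tested with camera in limma 3.58.1 with the preset correlation between genes of 0.01, and again with a correlation estimated from the data. Camera compares the mean test statistic of the genes of a list with that of the other genes, and the adjusted p is over the lists of a comparison. Members past the threshold were counted over all genes tested and adjusted over the list alone. The rule named Dusp1 first and in each comparison the 6 largest rises and 6 largest falls among genes past the threshold whose average log2 CPM was at least 1 and whose groups did not overlap. It also named up to 4 members of each list by p and all tested DUSP genes. It left 856 pairs of gene and comparison, from which 319 were picked as examples for the text after their values were seen, not all of which are named, so the examples lean towards clear changes. Some results are not reported here. Genes named outside the rule are said to be so.

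Positions of mouse genes were taken from GENCODE M21 on GRCm38, the assembly also called mm10, by symbol, and 99.0% of tested mouse genes had one. No human positions were used. Calls near Dusp1 were counted within 20 Mb on either side and compared with the rest of the genome by Fisher's exact test, and with windows of the same width around each tested gene of the other chromosomes. Overlap between mouse and A431 used genes with the same symbol apart from case. The alternatives were size factors of the RLE kind, no filter, DESeq2, the replicate number as a block, a threshold of 0.1 for the overlap, a fit of only the groups compared, and leaving out each library in turn. A covariate for Y chromosome counts and a run without genes near Dusp1 were added after the data were seen. Figures were drawn with matplotlib 3.10.9.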

Results

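RNA was measured in 17 libraries to ask what the loss of DUSP1 changes in squamous cell carcinoma (SCC) of the skin and in the cells around the tumour. DUSP1 is a dual-specificity phosphatase that removes phosphate from MAP kinases and so switches them off. The mouse part held 11 libraries from skin and skin tumours of animals treated with DMBA and TPA, a carcinogen and a tumour promoter. They were 3 libraries of wild-type (WT) skin, 3 of WT SCC, 3 of papilloma labelled Dusp1 knockout (KO) and 2 of SCC labelled KO. The human part held 6 libraries of A431, an established line of squamous carcinoma cells. In each arm 100000 cells were injected into the skin of mice, grown for 3 weeks and recovered, and mouse cells were depleted before RNA was taken. There were 3 control libraries, which carried a guide RNA against a gene foreign to the cells, and 3 DUSP1 KO libraries. Counts summed to 34.4 to 47.9 M (units of 1e6) per mouse library and 41.2 to 53.5 M per A431 library. Between libraries of a group the counts of a typical mouse gene varied by 36.6% and those of a typical A431 gene by 6.11%, as the biological coefficient of variation. The labels do not say whether libraries of a group came from separate animals or cultures, so the p-values measure the spread between these libraries. In WT skin and in SCC labelled KO the libraries differed in Y chromosome counts, as given below, so each of these groups held more than 1 animal, while in the other groups the spread may be technical.

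The targeted gene was examined first. Mouse Dusp1 (ENSMUSG00000024190.7) lies on the minus strand of chromosome 17, from 26505590 to 26562128 in GRCm38. Its level was 94.1, 109 and 52.4 counts per 1e6 counts (CPM) in the WT skin libraries and 73.3, 83.7 and 66.6 CPM in the WT SCC libraries. It was 129, 109 and 109.6 CPM in the papillomas labelled KO and 139 and 174 CPM in the carcinomas labelled KO. Dusp1 transcript was therefore not lower in any of the 5 libraries labelled KO than in the WT carcinomas. It was 2.11-fold higher in the carcinomas labelled KO than in WT carcinomas (log2 fold change 1.07 ± 0.25 (SE), adjusted p = 0.0284), a call that was lost when any 1 of the 5 libraries was left out (adjusted p 0.0718 to 0.144). The other contrasts did not pass (papilloma labelled KO against WT SCC 0.64, adjusted p = 0.152). The counts do not show which part of the gene was read, so they neither establish nor exclude the knockout, and every mouse direction below is that of the labels. In A431 cells the label and the transcript went together. DUSP1 was at 471, 467 and 485 CPM in the control libraries and at 73.6, 71.0 and 77.1 CPM in the KO libraries, 6.42-fold lower (log2 fold change -2.68 ± 0.05, adjusted p = 4.89e-17).

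**Figure D1:**
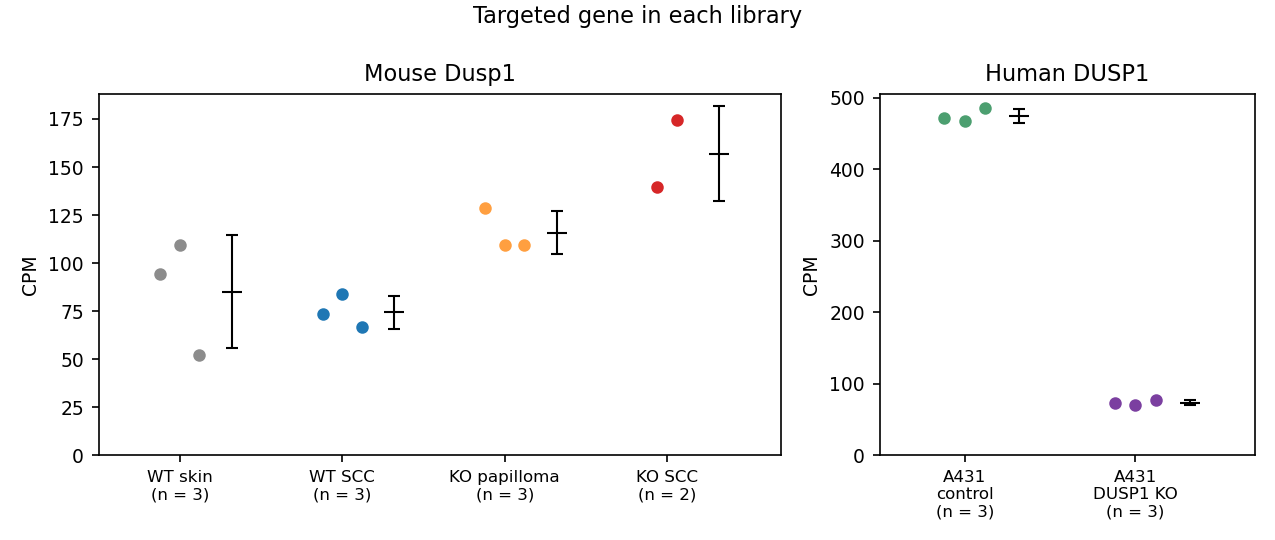
Counts per 1e6 counts (CPM, y axes, from 0) of mouse Dusp1 and human DUSP1 in each library (points) of each group (x axes), with the group mean and SD (crossbars). The 5 mouse libraries labelled KO lie between 109 and 174 CPM, above the 3 WT SCC libraries, while the 3 A431 KO libraries lie between 71.0 and 77.1 CPM, below the 3 control libraries.

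Carcinomas labelled KO were compared with WT carcinomas, the one pair of groups with the same lesion type and different genotype labels. Counts of Y chromosome genes were 4779 in KO SCC replicate 2 and 0 in KO SCC replicate 1 and the WT carcinomas. Sex, as read from these counts, and genotype label therefore partly went together here. KO SCC replicate 2 also held 15.3 CPM of the X chromosome gene Xist, chosen after its values were seen. KO SCC replicate 1 held 203 CPM and the WT carcinomas 404 to 497 CPM. The other libraries with Y chromosome counts, WT skin replicates 1 and 2, held 0.0745 and 0.705 CPM. Why KO SCC replicate 2 held both was not tested. The lists of keratinocyte differentiation and cholesterol synthesis were called higher in the carcinomas labelled KO, and those of B and plasma cells, TGF-beta targets and hypoxia lower, with a preset correlation between genes, and none of them with an estimated one. Il33, a cytokine that epithelial cells release on damage, rose from 33.8 ± 2.05 to 238 ± 19 CPM (log2 fold change 2.82 ± 0.25, adjusted p = 0.000279). Il1f6, which encodes IL-36 alpha, rose from 32.7 ± 7.31 to 299 ± 79.1 CPM (adjusted p = 0.000279). The immunoglobulin light chain gene Igkc fell from 133 ± 1.53 to 10.3 ± 1.93 CPM (log2 fold change -3.70 ± 0.59, adjusted p = 0.00549). All values here are mean ± SD over 2 libraries labelled KO and 3 WT libraries, and log2 fold changes are ± SE.

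Of the 26 tested members of the keratinocyte differentiation list, 10 rose, 1 fell and 15 did not pass over all genes tested. Adjusted over the list alone, 16 rose and 1 fell (camera adjusted p = 1.61e-08, and adjusted p = 0.243 with an estimated correlation). Cdsn, the adhesion protein of corneodesmosomes, rose 4.19-fold (log2 2.07 ± 0.24, adjusted p = 0.00109), and it lies within 20 Mb of Dusp1. The desmosomal cadherin gene Dsc1 rose 4.11-fold, the barrier lipid transporter gene Abca12 2.46-fold and the envelope crosslinking enzyme gene Tgm1 2.29-fold. The 1 member that fell was Krt10, an early differentiation keratin, which went from 975 ± 75.9 to 324 ± 139 CPM. It was outside the naming rule and was chosen after its values were seen. Of the list of hyperproliferation keratins and stress-induced barrier genes, 5 of 14 rose and none fell, and 11 rose adjusted over the list alone (adjusted p = 1.91e-09, and adjusted p = 0.153 with an estimated correlation). Those that rose were not keratins. They included Il1f6, the late cornified envelope gene Lce3c (8.33-fold, adjusted p = 0.00541), the small proline-rich protein gene Sprr2d (8.96-fold) and the S100 protein gene S100a7a (3.57-fold). Keratin and junction genes of internal and simple epithelia rose in 4 of 10, 6 adjusted over the list alone (adjusted p = 1.18e-05, and adjusted p = 0.105 with an estimated correlation). Krt13 went from 2028 ± 182 to 15188 ± 291 CPM (7.49-fold, adjusted p = 0.0164) and Krt4 rose 10.8-fold (adjusted p = 0.00648). Among basal keratinocyte genes, 1 of 12 fell, the stem cell keratin Krt15 by 2.37-fold (adjusted p = 0.00313), and 3 adjusted over the list alone (adjusted p = 0.00420, and adjusted p = 0.567 with an estimated correlation).

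Cholesterol synthesis genes rose in 8 of 14 members and fell in none, and 11 rose adjusted over the list alone (adjusted p = 1.91e-09, and adjusted p = 0.192 with an estimated correlation). Insig1, a sterol-regulated gene whose product restrains the pathway, rose 2.91-fold (log2 1.54 ± 0.22, adjusted p = 0.00368). Idi1, an isomerase of the pathway, rose 3.33-fold. Of 20 inflammatory cytokine genes 3 rose and 5 did adjusted over the list alone (adjusted p = 0.00140, and adjusted p = 0.480 with an estimated correlation). These were Il33, Il18 (2.38-fold) and Il1rn (2.59-fold), the last of which encodes an antagonist of the IL-1 receptor. Mitochondrially encoded transcripts rose in 5 of 13, 9 adjusted over the list alone (adjusted p = 3.31e-07, and adjusted p = 0.480 with an estimated correlation). mt-Nd1 went from 3316 ± 632 to 7649.8 ± 191 CPM. The proliferation list was called higher while 1 of its 24 members rose, the mitotic kinase gene Bub1 (1.99-fold), and 0 adjusted over the list alone (adjusted p = 2.13e-05, and adjusted p = 0.567 with an estimated correlation).

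Among TGF-beta targets 6 of 16 fell, 8 adjusted over the list alone, and none rose (adjusted p = 3.31e-07, and adjusted p = 0.153 with an estimated correlation). Thbs1, a secreted matrix glycoprotein gene, fell from 370.1 ± 16.3 to 110.5 ± 6.94 CPM (log2 -1.74 ± 0.27, adjusted p = 0.00484), and Ltbp2, of the family of latent TGF-beta binding proteins, fell 3.51-fold. Hypoxia and glycolysis genes fell in 4 of 18 (adjusted over the list alone 9 fell and 1 rose, adjusted p = 7.94e-05, and adjusted p = 0.567 with an estimated correlation). Ndrg1 went from 456 ± 51.9 to 137 ± 7.98 CPM (adjusted p = 0.00580) and the carbonic anhydrase gene Car9 fell 3.29-fold. Of 26 MAP kinase targets and feedback genes 6 fell and 1 rose (7 and 1 adjusted over the list alone, adjusted p = 0.00156, and adjusted p = 0.406 with an estimated correlation). The immediate early genes Egr1 (log2 -1.68), Jun (-0.82) and Jund (-0.79) fell, and Maff rose (0.80). In the DUSP family Dusp9 rose (log2 1.67) and Dusp10 fell (-1.43) beside the rise of Dusp1, and the remaining 7 did not pass. The list as a whole did not pass (adjusted p = 0.854). Dusp6, a negative feedback gene of ERK, was at -1.32 (adjusted p = 0.0626), past the threshold with DESeq2 (-1.28, adjusted p = 0.00423).

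Markers of other cell types moved with these groups. B and plasma cell genes fell in 3 of 13 (3 adjusted over the list alone, adjusted p = 0.00156, and adjusted p = 0.243 with an estimated correlation), Igkc together with Jchain (12.4-fold) and Mzb1 (5.11-fold). Fibroblast and matrix genes fell in 2 of 18, the actin gene Acta2 by 2.80-fold (3 adjusted over the list alone, adjusted p = 0.000881, and adjusted p = 0.567 with an estimated correlation). Macrophage genes fell in 1 of 18, the lysozyme gene Lyz2 by 3.93-fold (adjusted over the list alone 5 fell and 1 rose, adjusted p = 0.00673, and adjusted p = 0.592 with an estimated correlation). Dendritic cell genes fell in 2 of 13 (adjusted over the list alone 3 fell and 1 rose, adjusted p = 0.0136, and adjusted p = 0.567 with an estimated correlation), the lectin gene Cd209a from 3.63 ± 1.34 to 0.126 ± 0.138 CPM. The summed CPM of this list was higher, at 209 and 193 in the carcinomas labelled KO against 158, 156 and 167 in WT SCC. A fit of only these 2 groups ended its call and that of melanocytes (camera adjusted p = 0.114 and 0.0565). Mast cell genes rose in 2 of 10, also adjusted over the list alone (adjusted p = 0.0228, and adjusted p = 0.567 with an estimated correlation). These were the tryptase genes Tpsab1, from 0.508 ± 0.256 to 31.1 ± 3.23 CPM, and Tpsb2, 2.30-fold, which lie near each other and within 20 Mb of Dusp1. Without the genes of that window the call of the mast cell list ended (adjusted p = 0.327), as did those of MHC class I (adjusted p = 0.780) and class II (adjusted p = 0.224). The window holds 2 of 10 mast cell, 7 of 15 class I and 6 of 12 class II members, so that run tests shorter lists. Antigen presentation by MHC class I fell in 2 of 15 (adjusted over the list alone 7 fell and 2 rose, adjusted p = 0.00997, and adjusted p = 0.567 with an estimated correlation), the transporter genes Tap1 (log2 -0.86) and Tapbp (-0.91), which lie in the same window. The MHC class II list was called lower with 0 of 12 members past the threshold over all genes tested or over the list alone (adjusted p = 0.0132, and adjusted p = 0.567 with an estimated correlation). Melanocyte genes fell in 1 of 8, Sox10 (1 adjusted over the list alone, adjusted p = 0.0228, and adjusted p = 0.567 with an estimated correlation). The fall of this list rested on KO SCC replicate 2, with a mean log2 CPM of 1.13 and -0.65 in KO SCC replicates 1 and 2 and of 1.40 to 1.66 in WT SCC, and the list did not pass without it (adjusted p = 0.259). With 1 library left out, the calls of the macrophage, dendritic cell, fibroblast and MHC class II lists also ended without KO SCC replicate 1 (adjusted p = 0.270, 0.0512, 0.0562 and 0.129) and that of mast cells without KO SCC replicate 2 or WT SCC replicate 1 (adjusted p = 0.242 and 0.0669). Skeletal muscle genes fell in 1 of 16 and 12 adjusted over the list alone (adjusted p = 0.000770, and adjusted p = 0.567 with an estimated correlation). The muscle troponin gene Tnnt3 was at 0.697, 1.89 and 20.5 CPM in WT SCC replicates 1, 2 and 3 and at 0.0866 and 0.0497 CPM in the carcinomas labelled KO.

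Over all 22371 genes tested, 1760 passed an adjusted p of 0.05, 1003 higher and 757 lower in the carcinomas labelled KO. Of these 554 were higher and 394 lower by at least 2-fold. The values of the groups did not overlap in 46.6% of genes, against 20% by chance. With the presence of Y chromosome counts as a covariate, chosen after the data were seen, 2187 genes passed, 1414 of them called in the main fit. Of 40 gene lists 8 were called higher and 12 lower with the preset correlation, and none with an estimated one (smallest adjusted p = 0.105, 6 lists at an unadjusted p under 0.05). The covariate ended the calls of the mast cell and melanocyte lists (camera adjusted p = 0.119 and 0.362). In 4 lists that were not called (cytotoxic lymphocytes, interferon response, immune checkpoints, EGFR ligands and receptors) the median, the mean and the test differed in sign. The count of genes fell to 975, 432 and 711 without WT SCC replicate 1, 2 or 3 and to 302 and 698 without KO SCC replicate 1 or 2, and was 3345 with DESeq2 and 4160 with these groups alone. Of 75 called genes among those picked as examples, not all of them named here, 17 stayed past the threshold under every alternative, among them Il33, Il1f6, Lce3c, Cdsn, Dsc1, Abca12, Krt4, Insig1, Ltbp2 and Krt15, while Tgm1, Idi1, Igkc, Thbs1 and Ndrg1 were among 9 that lost it only without KO SCC replicate 1 (adjusted p 0.0515 to 0.132). Egr1 lost it only without KO SCC replicate 2, where 3 such genes had adjusted p 0.0540 to 0.0730, and the calls of Dusp9, Dusp10, Krt13 and Tap1 were lost under more than 1 alternative.

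**Figure D2:**
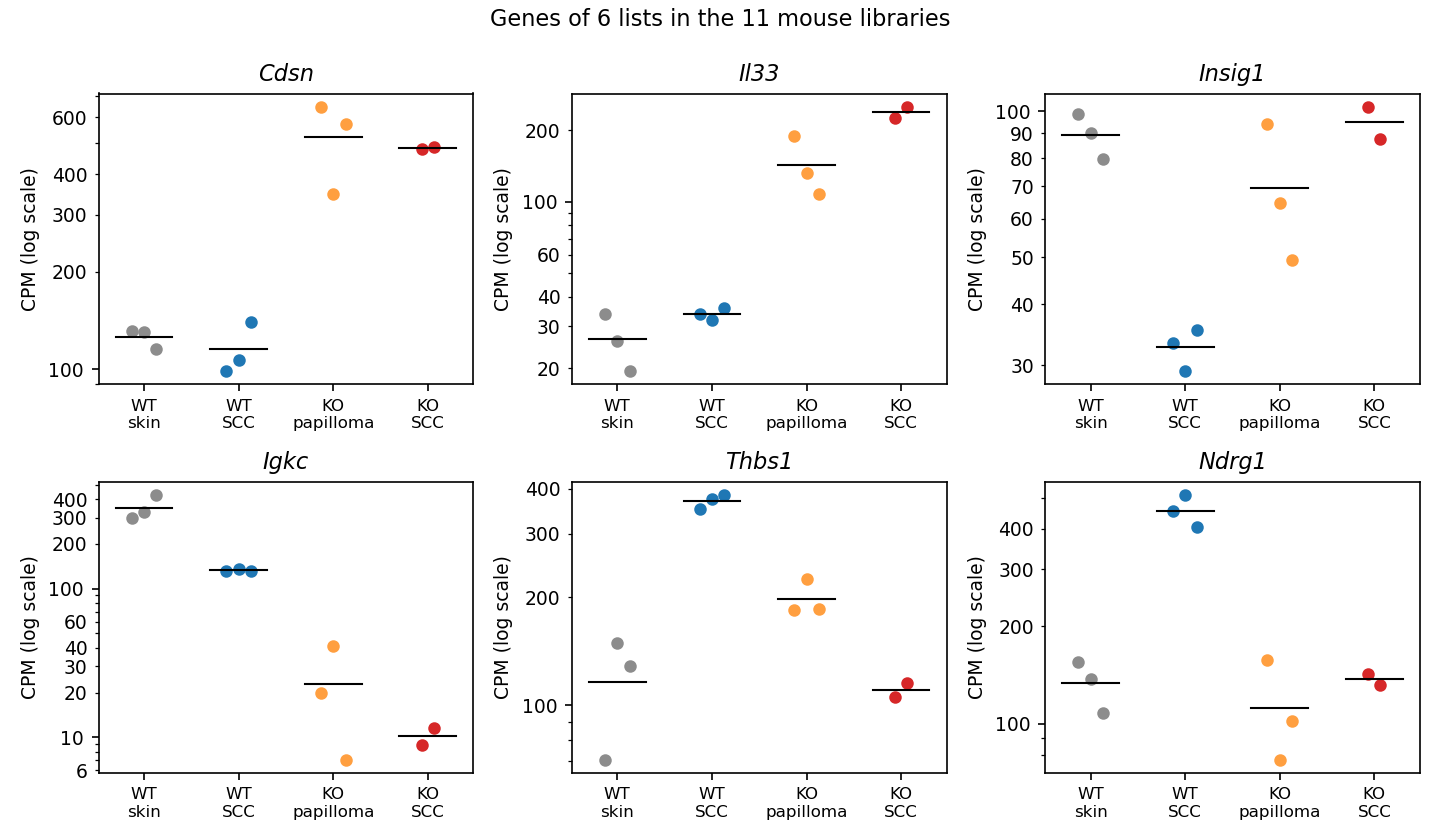
Counts per 1e6 counts (CPM, y axes, log scale) of Cdsn, Il33, Insig1, Igkc, Thbs1 and Ndrg1 in each of the 11 mouse libraries (points) by group (x axes), with group means (lines). In the carcinomas labelled KO, Cdsn, Il33 and Insig1 lie above and Igkc, Thbs1 and Ndrg1 below the WT SCC libraries.

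Among the genes of largest change were some whose position or sequence bears on how they are read. Dynlt1b, a dynein light chain gene with close paralogs, was at 0.441 ± 0.0626 CPM in WT carcinomas and at 37.6 ± 0.321 CPM in those labelled KO (adjusted p = 1.36e-06). The pseudogene Atp6v0c-ps2 on chromosome 6 was at 1.03 ± 0.236 and 109.5 ± 10.2 CPM. Its parent gene Atp6v0c, 2.37 Mb from Dusp1, was at 51.8 ± 7.0 and 10.8 ± 0.687 CPM and was chosen after its values were seen. Summed, the pair stood at 30.3 to 58.6 CPM in the WT libraries and at 97.9 to 156 CPM in those labelled KO. The predicted genes Gm9825 (0.220 ± 0.173 against 21.4 ± 2.63 CPM) and Gm7850 (19.9 ± 2.68 against 0.361 ± 0.0194 CPM) also separated the labels. Counting of reads that match more than 1 copy is not given in the sources used here, so the values of such genes are uncertain. The gene 2310061N02Rik had 0 counts in the WT carcinomas (3 counts would be at most 0.0871 CPM per library) and 12.3 ± 10.5 CPM in the carcinomas labelled KO.

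Of 656 tested genes within 20 Mb (20 x 1e6 bases) of Dusp1 on chromosome 17, 74 (11.3%) were called between the carcinomas, against 7.78% of genes elsewhere. The odds ratio was 1.51, with a 95% confidence interval of 1.16 to 1.93 (two-sided Fisher exact test, p = 0.00192, adjusted p = 0.00511 over 8 tests). Between papillomas labelled KO and WT carcinomas it was 1.64 (1.21 to 2.19). These contrasts share the WT SCC libraries, so their odds ratios are not independent. Between WT carcinomas and WT skin it was 0.807 (0.683 to 0.951). By chromosome, 9.82% and 7.21% of genes on chromosome 17 were called in the contrasts of carcinomas and of papillomas labelled KO with WT carcinomas, below the 10.4% and 7.31% on chromosome 18. The share called within 5, from 5 to 10 and from 10 to 20 Mb was 13.7%, 10.4% and 8.28% in the carcinomas and 11.7%, 3.48% and 9.47% in the papilloma contrast. The gene Ergic1, chosen after its values were seen, whose start at 26561489 overlaps that of Dusp1 on the other strand, was at log2 -0.63 (adjusted p = 0.0476), and without a stated strand setting its reads and those of Dusp1 cannot be told apart there.

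**Figure D3:**
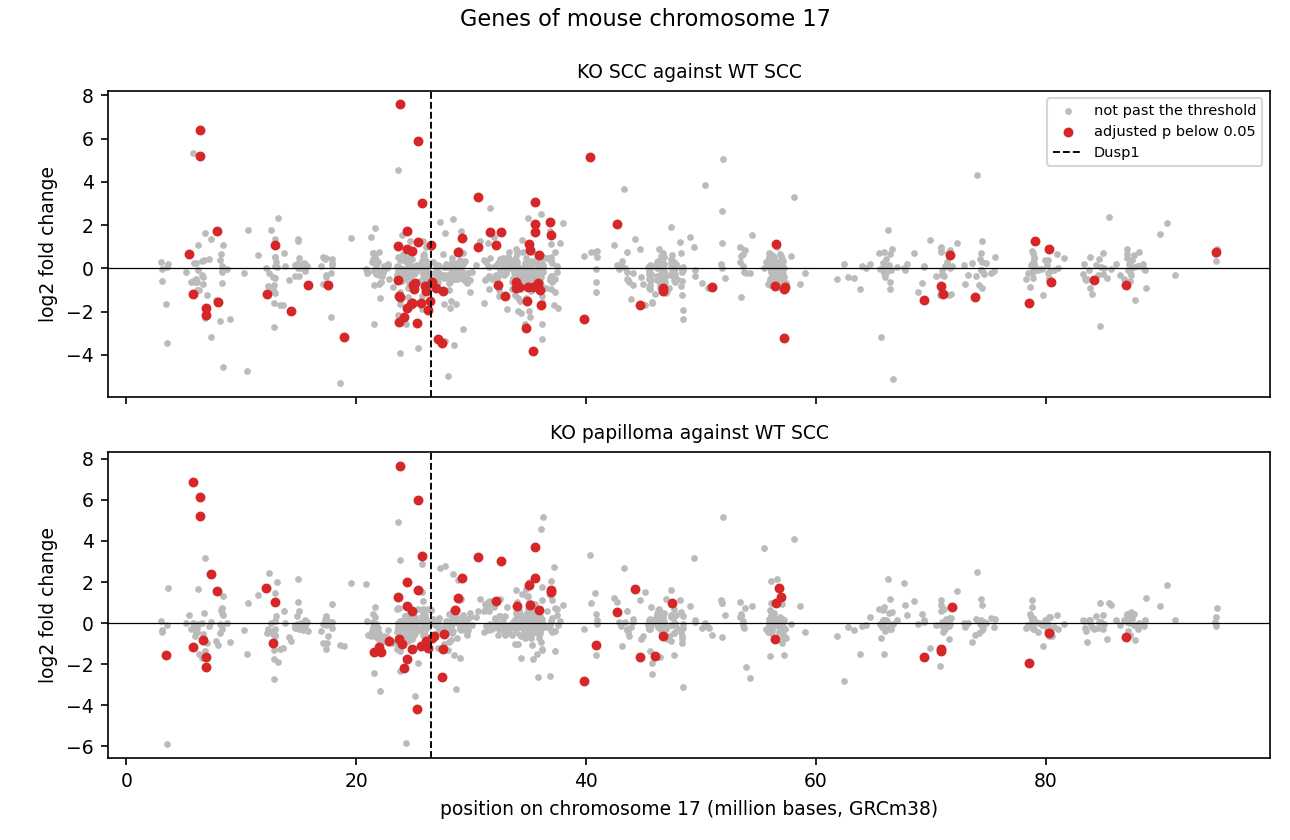
Log2 fold change (y axes) of tested genes along mouse chromosome 17 (x axis, Mb, GRCm38) in KO SCC against WT SCC (upper panel) and KO papilloma against WT SCC (lower panel), with genes past an adjusted p of 0.05 in red and a dashed line at Dusp1. Calls lie on both sides of Dusp1 and go in both directions, and 11.3% of genes within 20 Mb were called in the upper panel.

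WT carcinomas were compared with WT skin to describe the tumour within 1 genotype. The carcinomas carried more transcript of keratins of activated epidermis, of EGFR ligands, of glycolysis genes and of cell cycle genes. They carried less of muscle, fat, hair follicle and sebaceous genes, all of which full-thickness skin holds, and several immune cell lists were called lower. The lists behind this were called with the preset correlation and none with an estimated one. Krt13, a keratin of internal epithelia, went from 2.27 ± 1.77 to 2028 ± 182 CPM (log2 9.82 ± 0.77, adjusted p = 1.19e-05). The chromatin protein gene Hmga2 went from 0.733 ± 0.343 to 40.5 ± 6.44 CPM (adjusted p = 5.70e-06), and the transcription factor gene Pitx1 rose 51.0-fold. Each group had 3 libraries.

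Hyperproliferation keratins and stress-induced barrier genes rose in 12 of 14, the same number adjusted over the list alone (adjusted p = 1.01e-06, and adjusted p = 0.207 with an estimated correlation), Krt6a by 9.18-fold, Krt6b by 9.41-fold and Krt16 by 8.69-fold. Basal keratinocyte genes rose in 10 of 12 and fell in 1, on either adjustment (adjusted p = 0.000170, and adjusted p = 0.309 with an estimated correlation). The integrin gene Itga6 rose 4.07-fold and the exception Krt15 fell 5.15-fold. Differentiation genes went both ways, 9 up and 11 down of 26 (9 and 12 adjusted over the list alone), and the list did not pass (adjusted p = 0.507). Flg2, of the filaggrin family, fell 97.1-fold while Tgm1 rose 3.65-fold. Hypoxia and glycolysis genes rose in 15 of 18 and fell in 1, on either adjustment (adjusted p = 2.62e-09, and adjusted p = 0.207 with an estimated correlation), with Car9 7.02-fold and the lactate dehydrogenase gene Ldha 3.14-fold higher. EGFR ligand and receptor genes rose in 6 and fell in 2 of 12, on either adjustment (adjusted p = 0.00147, and adjusted p = 0.207 with an estimated correlation), with Hbegf 9.23-fold, Areg 7.60-fold and Nrg1 12.5-fold higher. Proliferation genes rose in 15 of 24, 17 adjusted over the list alone, and none fell (adjusted p = 8.36e-07, and adjusted p = 0.370 with an estimated correlation).

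MAP kinase targets and feedback genes rose in 11 and fell in 5 of 26 (12 and 5 adjusted over the list alone, adjusted p = 0.000139, and adjusted p = 0.207 with an estimated correlation). The AP-1 subunit gene Fosl1 went from 1.97 ± 0.265 to 29.2 ± 3.78 CPM (adjusted p = 3.91e-06) and Phlda1 rose 5.34-fold. Of the 10 DUSP genes 5 rose and 2 fell, on either adjustment (adjusted p = 0.0114, and adjusted p = 0.207 with an estimated correlation). Dusp6 rose 5.72-fold, Dusp7 4.42-fold and Dusp5 3.24-fold, Dusp2 fell 4.59-fold, and Dusp1 itself was at log2 -0.19 (adjusted p = 0.515, and -0.44 with adjusted p = 0.0481 without WT skin replicate 3). TGF-beta targets rose in 9 and fell in 2 of 16, on either adjustment (adjusted p = 0.0271, and adjusted p = 0.322 with an estimated correlation), Thbs1 3.19-fold higher. Targets of p53 rose in 10 and fell in 2 of 15 (adjusted p = 0.000596, and adjusted p = 0.247 with an estimated correlation), with Mdm2 1.76-fold higher, and heat shock and stress genes rose in 9 and fell in 2 of 16 (adjusted p = 0.00342, and adjusted p = 0.207 with an estimated correlation), Hspa8 2.2-fold higher. Both counts were unchanged adjusted over the list alone.

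All 16 skeletal muscle genes fell (adjusted p = 2.62e-09, and adjusted p = 0.207 with an estimated correlation), the calcium pump gene Atp2a1 from 535 ± 132 to 2.13 ± 3.07 CPM. Of 11 fat genes 10 fell and 1 rose (adjusted p = 0.000433, and adjusted p = 0.322 with an estimated correlation), the leptin gene Lep from 59.0 ± 50.7 to 0.222 ± 0.228 CPM, and all 8 nerve and Schwann cell genes fell (adjusted p = 1.80e-07, and adjusted p = 0.207 with an estimated correlation). These counts held adjusted over the list alone. Hair follicle genes fell in 16 of 18 (17 adjusted over the list alone, adjusted p = 0.00207, and adjusted p = 0.566 with an estimated correlation). Krt25 was at 6.03, 401 and 2420 CPM in the skin libraries and at 0.0581, 0 and 0.0699 CPM in the carcinomas, and Krt72, Krt26 and Krt33a had 0 counts in all 3 carcinomas, where 3 counts would be at most 0.0871 CPM per library. Sebaceous genes fell in 9 of 10 (10 adjusted over the list alone, adjusted p = 2.51e-05, and adjusted p = 0.247 with an estimated correlation), the desaturase gene Scd1 by 17.5-fold. Interferon response genes fell in 22 of 26 (24 adjusted over the list alone, adjusted p = 4.34e-07, and adjusted p = 0.322 with an estimated correlation), Usp18 by 8.21-fold, and MHC class I genes in 12 of 15 (12 fell and 1 rose adjusted over the list alone, adjusted p = 0.000109, and adjusted p = 0.247 with an estimated correlation), B2m by 2.77-fold. The MHC class I call ended without genes within 20 Mb of Dusp1 (adjusted p = 0.285). That window holds 7 of the 15 members and both groups are WT, so this shows what the remaining members give and no effect of the allele. Markers of immune cells also fell: T cells in 15 of 20 (2 rose, adjusted p = 0.00197, and adjusted p = 0.481 with an estimated correlation), macrophages in 11 of 18 (1 rose, adjusted p = 0.010, and adjusted p = 0.570 with an estimated correlation) and mast cells in 8 of 10 (adjusted p = 4.16e-06, and adjusted p = 0.247 with an estimated correlation), all unchanged adjusted over the list alone. Cd163 of macrophages fell 8.45-fold, the chymase gene Cma1 7.48-fold and Cd8b1 15.5-fold. In the T cell list most members fell but their total did not. Its summed CPM was 260, 220 and 166 in WT skin replicates 1, 2 and 3 and 238, 215 and 207 in those of WT SCC. The summed CPM of macrophages overlapped too, at 1012 to 2402 in WT skin and 1135 to 1294 in WT SCC. The neutrophil list did not pass (camera adjusted p = 0.155).

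Without WT skin replicate 3 the macrophage and TGF-beta target lists did not pass (adjusted p = 0.0728 and 0.0730). In total 9054 genes passed, 3771 higher and 5283 lower in the carcinomas, 1366 and 4267 of them by at least 2-fold. The groups did not overlap in 54.7% of genes, against 10% by chance, and the median log2 fold change of all genes was -0.16. Of 40 lists 10 were called higher and 17 lower, none with an estimated correlation (smallest adjusted p = 0.207, 9 lists at an unadjusted p under 0.05), and 3 lists that were not called (neutrophils, simple epithelial keratins, cholesterol synthesis) had a median, mean and test that differed in sign. Y chromosome genes held 6624 and 9552 counts in WT skin replicates 1 and 2 and 7 in replicate 3, and 0 in the WT carcinomas, so sex and lesion partly went together. With the presence of Y chromosome counts as a covariate, chosen after the data were seen, 6101 genes passed.

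Papillomas labelled KO were set against WT carcinomas. No WT papilloma was among the libraries, so lesion type and genotype label change together and a difference cannot be assigned to either. The lists of keratinocyte differentiation, mast cells and cholesterol synthesis were called higher in the papillomas and that of hypoxia lower with the preset correlation. Keratinocyte differentiation genes rose in 18 of 26 and 23 adjusted over the list alone, with none lower (adjusted p = 9.47e-39), the one list of this contrast called with an estimated correlation as well (adjusted p = 0.0209). The cornified envelope gene Lce1a1 rose from 32.3 ± 8.09 to 263 ± 5.43 CPM (log2 3.03 ± 0.27, adjusted p = 0.000145) and the hornerin gene Hrnr from 53.6 ± 13.4 to 442 ± 160.1 CPM (adjusted p = 0.000241). Krt2 rested on 1 library, at 39 CPM in KO papilloma replicate 2 and 0.50 and 0.63 CPM in replicates 1 and 3. Mast cell genes rose in 6 of 10 and 9 adjusted over the list alone (adjusted p = 1.90e-09, and adjusted p = 0.170 with an estimated correlation), the chymase gene Cma1 by 2.64-fold and the carboxypeptidase gene Cpa3 by 2.51-fold. Cholesterol synthesis genes rose in 8 of 14 and 11 adjusted over the list alone (adjusted p = 1.24e-10, and adjusted p = 0.168 with an estimated correlation), Mvd by 2.59-fold. Cytokine genes rose in 4 of 20, on either adjustment (adjusted p = 0.00595, and adjusted p = 0.503 with an estimated correlation), with Il18 5.17-fold and Il33 4.25-fold higher.

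Hypoxia and glycolysis genes fell in 7 of 18 and 10 adjusted over the list alone (adjusted p = 6.08e-12, and adjusted p = 0.170 with an estimated correlation), Ndrg1 by 4.07-fold (adjusted p = 0.000838), Car9 by 4.43-fold and the mitophagy gene Bnip3 by 2.47-fold. TGF-beta targets fell in 3 of 16 (4 adjusted over the list alone, adjusted p = 0.000224, and adjusted p = 0.170 with an estimated correlation), Thbs1 by 1.87-fold, and B and plasma cell genes in 3 of 13, on either adjustment (adjusted p = 0.0134, and adjusted p = 0.324 with an estimated correlation), Igkc by 5.87-fold. Hyperproliferation genes rose in 4 of 14 (8 adjusted over the list alone, adjusted p = 5.36e-09, and adjusted p = 0.168 with an estimated correlation), simple epithelial keratins in 2 of 10 (3, adjusted p = 0.000335, and adjusted p = 0.119 with an estimated correlation) and mitochondrial transcripts in 3 of 13 (7, adjusted p = 1.05e-05, and adjusted p = 0.503 with an estimated correlation). Macrophage genes fell in 1 of 18 on either adjustment (adjusted p = 0.00207, and adjusted p = 0.676 with an estimated correlation), MAP kinase targets in 1 of 26 (7 fell and 1 rose adjusted over the list alone, adjusted p = 0.0177, and adjusted p = 0.503 with an estimated correlation) and muscle genes in 2 of 16 (10, adjusted p = 0.000159, and adjusted p = 0.676 with an estimated correlation). The mean log2 CPM of the muscle list was -1.08, 0.53 and 3.78 in WT SCC replicates 1, 2 and 3 and -0.79 to -0.65 in the papillomas, and adjusted p was 0.0305 without WT SCC replicate 3. Interferon and hair follicle lists were called higher with 0 of 26 and 0 of 18 members past the threshold over all genes tested (adjusted p = 0.000588 and 1.05e-05, and adjusted p = 0.676 and 0.637 with an estimated correlation), and 0 and 9 rose adjusted over the list alone. The papilloma libraries differed, with mean log2 CPM of 3.17, 2.29 and 2.02 for interferon and 4.13, 3.01 and -0.54 for hair follicle in replicates 1, 2 and 3, against 1.56 to 2.09 and -1.44 to -1.21 in WT SCC. The interferon list did not pass without KO papilloma replicate 1 (adjusted p = 0.0816), and that of MAP kinase targets did not without KO papilloma replicate 1 or WT SCC replicate 2 (adjusted p = 0.0781 and 0.0881). Of the DUSP family Dusp9 rose (log2 1.30) and Dusp4 (-1.37) and Dusp10 (-1.35) fell. In total 780 genes were higher and 395 lower, and 9 lists higher and 6 lower. Other splits of the same libraries gave as many called lists or more, as given below, so the number of lists does not set these labels apart. The groups did not overlap in 26.6% of genes, against 10% by chance. The count of 1175 genes fell to 654, 478 and 701 without WT SCC replicate 1, 2 or 3 and to 677 without KO papilloma replicate 1, and was 1797 with these 2 groups alone, 1854 without a filter and 2178 with DESeq2. Of 53 called genes picked as examples, 23 stayed past the threshold under every alternative, among them Lce1a1, Hrnr, Il33, Il18, Mvd, Ndrg1, Car9 and Bnip3, while Cma1 and Dusp4 were among 6 that lost the call only without WT SCC replicate 2 (adjusted p 0.0508 to 0.0555) and Igkc lost it only without KO papilloma replicate 1 (adjusted p = 0.0511). The lists of immune checkpoints, the DUSP family, heat shock and sex-linked genes, none of them called, had a median, mean and test that differed in sign.

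Carcinomas and papillomas labelled KO were compared to describe lesion stage within that label. The carcinomas carried less transcript of the suprabasal keratins and of filaggrin. Krt10 fell from 2433 ± 306 to 324 ± 139 CPM (log2 -2.91 ± 0.36, adjusted p = 0.0196), Krt1 from 3220.2 ± 856 to 411 ± 72.3 CPM (adjusted p = 0.0300) and Flg, a precursor of the barrier protein filaggrin, from 578 ± 70.8 to 82.1 ± 1.87 CPM (adjusted p = 0.0162). Differentiation genes fell in 4 of 26 and 12 adjusted over the list alone (adjusted p = 5.26e-12, and adjusted p = 0.292 with an estimated correlation). MHC class I genes fell in 1 of 15, Tap1 by 2.2-fold, and 9 adjusted over the list alone (adjusted p = 1.44e-08, and adjusted p = 0.292 with an estimated correlation), a call that ended without genes within 20 Mb of Dusp1 (adjusted p = 0.114). Of the 15 members 7 lie in that window. Interferon genes fell in 1 of 26 on either adjustment (adjusted p = 1.48e-05, and adjusted p = 0.566 with an estimated correlation). T cell genes moved with these, 0 past the threshold over all genes and 4 of 20 lower adjusted over the list alone (adjusted p = 5.49e-05, and adjusted p = 0.566 with an estimated correlation), as did mast cell genes with 4 of 10 (adjusted p = 0.000253, and adjusted p = 0.566 with an estimated correlation). Among 11 genes that rose were the membrane protein gene Emp1 (2.2-fold), the claudin gene Cldn8 (3.56-fold) and Ly6c1 (2.81-fold). Only 64 genes passed, 53 of them lower, with 3493 at an unadjusted p under 0.05, and groups that did not overlap in 31.6% of genes against 20% by chance. The count was 842 with DESeq2 (41.1% higher against 17.2%), 611 without a filter (34.4% higher), 240 with the Y chromosome covariate (41.3% higher), 12 and 0 without KO papilloma replicate 1 or 3 and 0 and 7 without KO SCC replicate 1 or 2. None of the 17 called genes picked as examples kept its call under every alternative. Of 16 lists called, 2 higher and 14 lower, none was called with an estimated correlation (smallest adjusted p = 0.292, 3 lists at an unadjusted p under 0.05), and the neutrophil and DUSP family lists, not called, had a median, mean and test that differed in sign. Y chromosome genes held 4779 counts in KO SCC replicate 2 and 0 in the other libraries labelled KO.

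**Figure D4:**
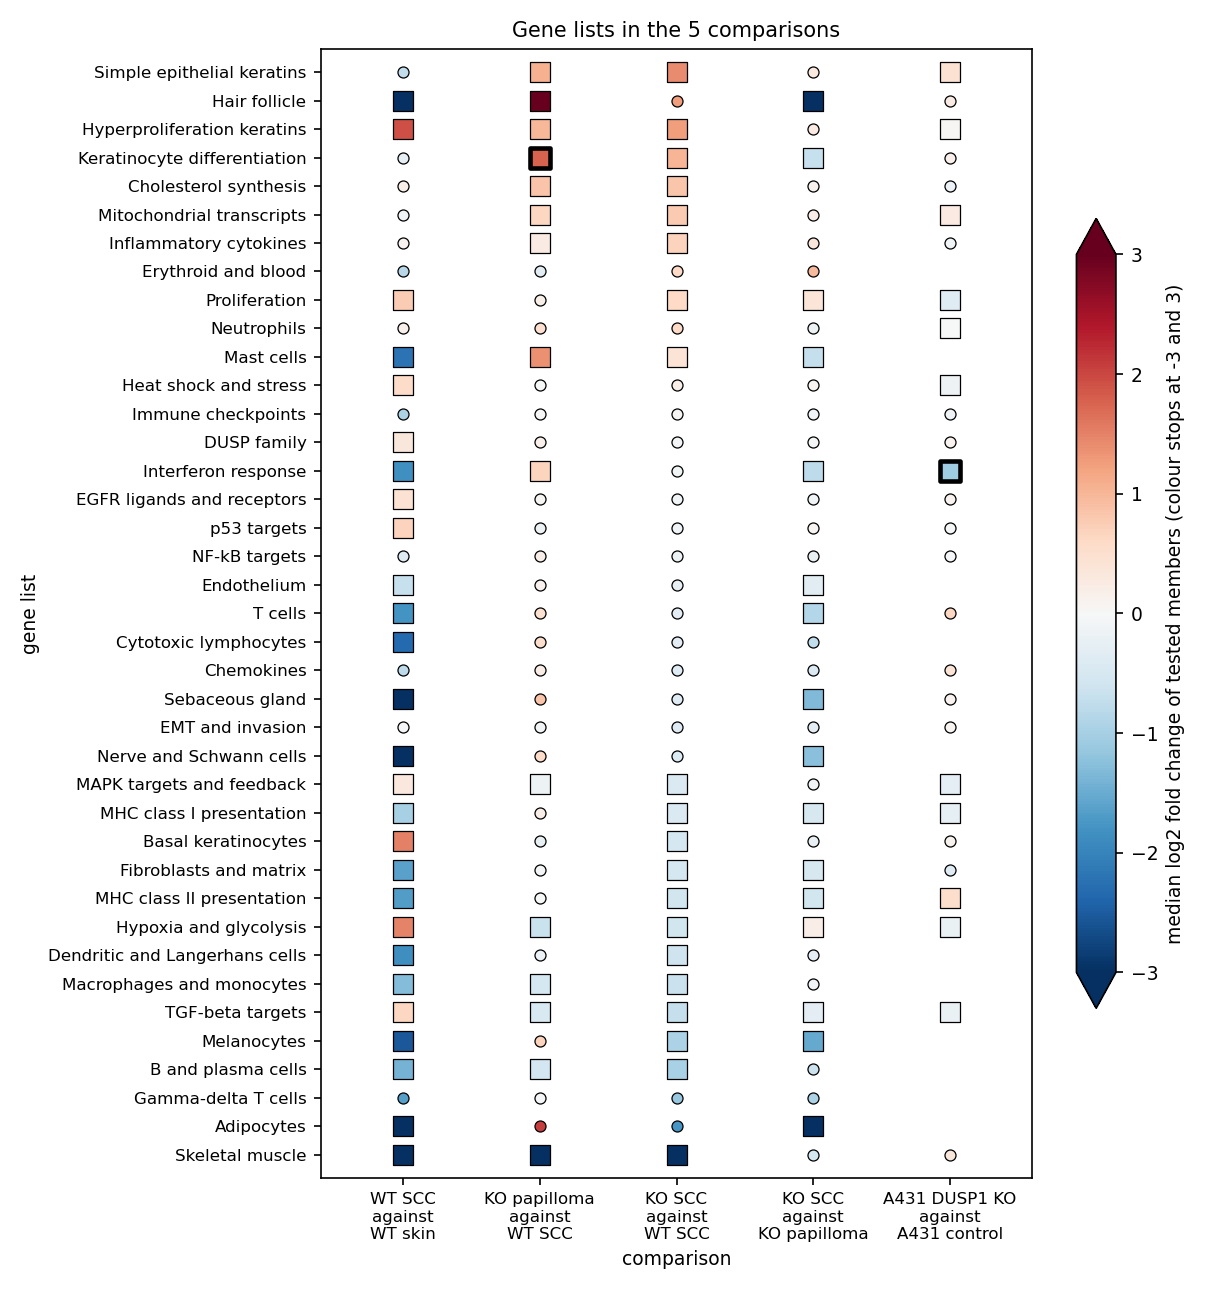
Median log2 fold change (colour) of the tested members of 39 gene lists (y axis) in the 5 comparisons (x axis), without the list of sex-linked genes. Squares mark lists past an adjusted p of 0.05 with the preset correlation, thick outlines those also past it with an estimated correlation, and circles those not past it, and thick outlines stand at keratinocyte differentiation in papilloma labelled KO against WT SCC and at the interferon response in A431 cells.

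In A431 xenograft cells the DUSP1 KO was set against the control guide. The lists of interferon response and MHC class I were called lower in the KO cells, and those of class II and simple epithelial keratins higher, with the preset correlation, and of these only the interferon response with an estimated one. Fibronectin (FN1) fell from 419 ± 19.2 to 58.5 ± 1.5 CPM (log2 -2.84 ± 0.05, adjusted p = 4.89e-17). Of the interferon response list 26 of 28 members fell and 27 did adjusted over the list alone (adjusted p = 2.25e-54), the one list of this contrast also called with an estimated correlation (adjusted p = 0.00314). IFIT1, which binds foreign RNA, fell 3.41-fold (log2 -1.77 ± 0.06), IFIT2 by 4.21-fold and IFI6 by 2.65-fold. The interferon-induced chemokine gene CXCL10 fell from 3.95 ± 0.701 to 0.565 ± 0.132 CPM (adjusted p = 1.45e-08). MHC class I genes fell in 11 and rose in 1 of 16, on either adjustment (adjusted p = 2.86e-05, and adjusted p = 0.176 with an estimated correlation), with HLA-B 1.71-fold and B2M 1.66-fold lower. MHC class II genes rose in 4 of 7, on either adjustment (adjusted p = 3.59e-05, and adjusted p = 0.0613 with an estimated correlation), the invariant chain gene CD74 from 1.15 ± 0.277 to 17.6 ± 1.49 CPM and HLA-DPA1 from 0.106 ± 0.0358 to 4.29 ± 0.535 CPM. Of these 4, CTSS did not pass with DESeq2 (adjusted p = 0.0712) and HLA-DMA did not without control replicate 2 (adjusted p = 0.0630). Each arm had 3 libraries.

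**Figure D5:**
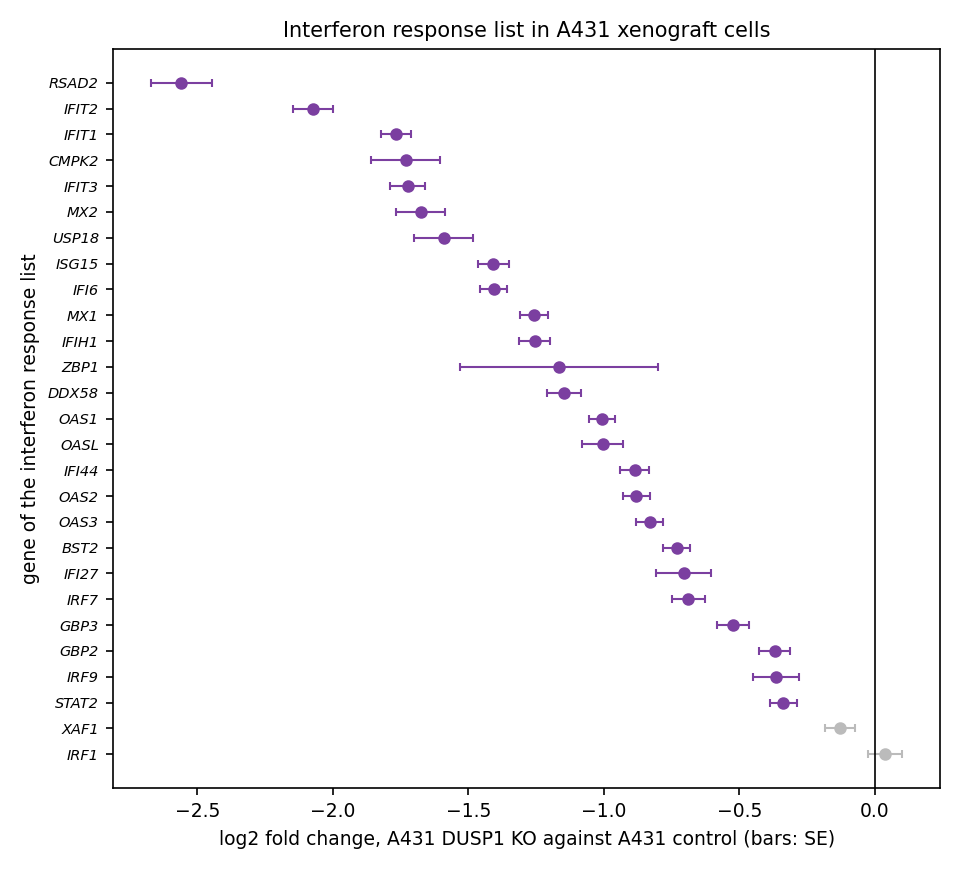
Log2 fold change with SE (x axis) of 27 of the 28 tested genes of the interferon response list (y axis), A431 DUSP1 KO against control, with genes past an adjusted p of 0.05 in purple and the others in grey. All drawn but XAF1 and IRF1 lie below 0 and past the threshold, RSAD2 lowest.

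Simple epithelial keratins rose in 6 and fell in 1 of 10 (7 and 1 adjusted over the list alone, adjusted p = 1.59e-07, and adjusted p = 0.0613 with an estimated correlation). KRT4 rose from 201 ± 2.81 to 772 ± 18.3 CPM (log2 1.94 ± 0.04, adjusted p = 6.19e-16) and KRT13 2.08-fold, and the adhesion gene EPCAM fell 1.48-fold. Hyperproliferation genes went both ways, 5 up and 4 down of 13 on either adjustment (adjusted p = 0.000794, and adjusted p = 0.211 with an estimated correlation). SPRR2A rose 2.61-fold and SPRR1A 2.26-fold. The late keratin KRT2 fell from 89.8 ± 0.185 to 13.5 ± 0.740 CPM while the epidermal protease gene KLK5 rose 2.96-fold, within a differentiation list that did not pass (13 up and 5 down of 25, 13 and 6 adjusted over the list alone, adjusted p = 0.139). Proliferation genes fell in 16 and rose in 2 of 24, on either adjustment (adjusted p = 2.86e-05, and adjusted p = 0.0613 with an estimated correlation), the cycling cell marker gene MKI67 by 1.57-fold. Hypoxia and glycolysis genes fell in 11 and rose in 1 of 18 (12 and 1 adjusted over the list alone, adjusted p = 3.35e-05, and adjusted p = 0.0613 with an estimated correlation), the hexokinase gene HK2 by 2.15-fold and NDRG1 by 1.54-fold, while CA9 rose 1.46-fold.

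MAP kinase targets and feedback genes fell in 14 and rose in 8 of 26 (14 and 10 adjusted over the list alone, adjusted p = 0.00217, and adjusted p = 0.176 with an estimated correlation). The AP-1 genes FOS (log2 -1.11) and FOSL2 (-0.81) fell and the ETS factor gene ETV4 rose (1.05). Of the DUSP family 5 rose and 3 fell, on either adjustment, and the list did not pass (adjusted p = 0.212). DUSP6 rose 1.79-fold (adjusted p = 7.25e-10), DUSP7 1.52-fold and DUSP9 2.27-fold, DUSP4 fell 1.48-fold and DUSP5 1.35-fold. The rises of DUSP2 (log2 0.22) and DUSP8 (0.56) did not pass with DESeq2 (adjusted p = 0.0610 and 0.148). EGFR, which A431 cells carry at a high level, fell from 2613 ± 93.1 to 1659 ± 32.6 CPM (adjusted p = 5.29e-10), within a list that did not pass (4 up and 3 down of 11, 5 and 3 adjusted over the list alone, adjusted p = 0.730). TGF-beta targets fell in 8 and rose in 3 of 15, on either adjustment (adjusted p = 0.00546, and adjusted p = 0.139 with an estimated correlation), the ligand gene BMP2 by 4.77-fold. Heat shock genes fell in 8 and rose in 3 of 16 (adjusted p = 0.0146, and adjusted p = 0.326 with an estimated correlation) and mitochondrial transcripts rose in 9 and fell in 1 of 13 (adjusted p = 0.0168, and adjusted p = 0.503 with an estimated correlation), both also adjusted over the list alone. The neutrophil list was called lower, with 3 down and 1 up of 7 (3 and 3 adjusted over the list alone, adjusted p = 0.00191, and adjusted p = 0.176 with an estimated correlation). Its MMP9, a matrix protease gene that tumour cells also express, fell from 85.3 ± 4.50 to 16.1 ± 1.79 CPM, and the collagenase gene MMP1, of another list, rose 3.35-fold. Matrix genes more typical of fibroblasts went both ways, 4 up and 7 down of 12 on either adjustment in a list that did not pass (adjusted p = 0.207), with DCN at 8.32 ± 0.532 CPM in control and 1.14 ± 0.117 CPM in KO cells and COL3A1 at 3.95 ± 0.348 and 0.428 ± 0.218 CPM. SPARC, chosen after its values were seen, rose from 0.154 ± 0.102 to 1.82 ± 0.191 CPM (adjusted p = 6.20e-07).

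In total 8617 of 18090 genes passed, 4178 higher and 4439 lower, of which 1099 and 376 changed by at least 2-fold. The groups did not overlap in 55.0% of genes, against 10% by chance, and 4 lists were called higher and 8 lower of 28. Lists of immune checkpoints, the DUSP family and EMT, none of them called, had a median, mean and test that differed in sign. The labels do not say whether the KO cells were a clone or a pool, so a difference between clones would enter these counts. The descriptions of all 3 KO libraries share a code, and those of replicates 2 and 3 end alike, so it is not known whether they are separate cultures.

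Calls in the mouse contrast of carcinomas and in A431 cells, which share no library, were compared over 11870 genes matched by symbol. Genes higher in both numbered 186 against 176 expected by chance (odds ratio 1.08, one-sided Fisher exact test, p = 0.193), and genes lower in both 173 against 179.6 (odds ratio 0.945, p = 0.742). Genes higher in mouse and lower in A431 numbered 253 against 229 (odds ratio 1.17, exact p = 0.0285), and those lower in mouse and higher in A431 162 against 138 (odds ratio 1.26, exact p = 0.00929). The odds ratio of genes higher in both was 1.17 without a filter (exact p = 0.0247) and 0.946 with DESeq2. That of genes higher in mouse and lower in A431 was 1.57 without a filter (exact p = 8.76e-12), 1.36 with DESeq2 (exact p = 1.08e-07) and 1.34 at a threshold of 0.1 (exact p = 1.05e-06), and that of genes lower in mouse and higher in A431 was 1.46, 1.36 and 1.28. Among genes picked as examples after their values were seen, KRT4, KRT13, SPRR2D and DUSP9 rose and THBS1, NDRG1 and PMEPA1 fell in both systems, while INSIG1 rose in the carcinomas labelled KO and fell in A431 KO cells. These examples do not stand for all matched genes. Over those, calls in the same direction were not in excess in the main fit. Calls in opposite directions were, at exact p-values under 0.05 that were not adjusted for the number of directions tested. Genes are not independent replicates, so these p-values describe the lists, and the mouse side rests on libraries whose Dusp1 transcript went against their label.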

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

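The test of the difference between the systems was planned, and the set of genes it ran on follows from picking genes as examples after their values were seen. In each of 14 genes picked in both systems, the log2 fold change of KO SCC against WT SCC in mouse was set against that of DUSP1 KO against control in A431. The difference was divided by its SE from the edgeR fits and read against a normal distribution, which gives p-values that are too small with so few libraries. It passed an adjusted p of 0.05 in 11 of them, and the 3 others were DUSP9, HSPA1A and TAP1. The SE of these genes was 0.182 to 0.617 in mouse and 0.0365 to 0.115 in A431. A call in mouse therefore takes a larger fold change than one in A431, and genes picked for their calls lean towards larger changes in mouse. The species, the cell mixture and the experiment differ together between the systems, and the mouse libraries labelled KO do not show lower Dusp1, so the differences are not assigned to any of these.

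The target itself differed most, with the mouse log2 fold change of DUSP1 3.76 above that of A431 (adjusted p = 3.37e-47). DUSP6 lay 2.15 lower in mouse, a difference of -2.15 (adjusted p = 1.88e-07), and DUSP10 differed by -1.34 (adjusted p = 0.000450). INSIG1, a sterol-regulated gene, rose in mouse and fell in A431, a difference of 1.90 (adjusted p = 8.65e-16). KRT13 (1.85, adjusted p = 0.00299), KRT4 (1.49, adjusted p = 0.0119) and SPRR2D (2.16, adjusted p = 0.000969) rose in both systems and more in mouse. THBS1 (-1.27, adjusted p = 9.80e-06), NDRG1 (-1.11, adjusted p = 0.000218) and PMEPA1 (-0.68, adjusted p = 0.00173) fell in both systems and more in mouse. Because the picking leans that way, the larger changes in mouse are not a result of their own. The mitochondrial gene MT-ND1 rose in both systems and differed by 0.56 (adjusted p = 0.0131).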

How the results depend on the processing

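The Y chromosome covariate and the run without genes near Dusp1 were chosen after the data were seen. For KO SCC against KO papilloma, 64 genes became 611 without a filter, 842 with DESeq2, 240 with the covariate, 1 with the replicate number as a block, and 0 to 84 when 1 library was left out. For KO SCC against WT SCC, 1760 became 3345 with DESeq2, 4160 with only the groups compared, 798 with the block and 302 to 975 with 1 library left out. For KO papilloma against WT SCC, 1175 became 1854 without a filter, 2178 with DESeq2, 1797 with only the groups compared and 478 to 1100 with 1 library left out. Where 1 KO SCC library is left, it is assumed to vary like the other groups. The replicate numbers carry no stated pairing and deviations of libraries with the same number did not go together (correlations from -0.41 to 0.17), so the block gives no paired result. Gene counts of WT SCC against WT skin and of A431 stayed within 1.5 times under each alternative, at 6101 to 9934 and 7435 to 9564. Without genes near Dusp1 the mouse counts were 1673, 8828, 62 and 1115 genes and 17, 25, 14 and 15 lists, where MHC class I and II in all but KO papilloma against WT SCC and mast cells in KO SCC against WT SCC lost their calls. That run takes out 7 of 15 class I and 6 of 12 class II members, so it cannot tell an effect of the locus from a shorter list. With an estimated correlation the lists called went from 20, 27, 16, 15 and 12 to 0, 0, 0, 1 and 1, and other alternatives moved these by less than 1.5 times. Similar numbers can hide lost calls. With the covariate 18 of the 20 lists of KO SCC against WT SCC and 14 of the 16 of KO SCC against KO papilloma kept theirs. The odds ratio for genes higher in mouse and A431 went from 1.08 to 1.17 without a filter (exact p = 0.0247), to 0.946 with DESeq2 and to 0.946 at a threshold of 0.1. The log2 fold change of Dusp1 in WT SCC against WT skin went from -0.19 to 0.32 with the covariate, and with 1 library left out from -0.44 (without WT skin replicate 3, adjusted p = 0.0481) to 0.018 (without WT skin replicate 2). Its call in KO SCC against WT SCC was lost with the block (adjusted p = 0.0580) and without each library (adjusted p 0.0718 to 0.144), and in KO papilloma against WT SCC it was gained without a filter (adjusted p = 0.0361), with the covariate (0.0394) and with only the groups compared (0.0152). Of the called genes picked as examples, 17 of 75, 80 of 88, 0 of 17, 23 of 53 and 75 of 80 kept their calls under all alternatives, in the order KO SCC against WT SCC, WT SCC against WT skin, KO SCC against KO papilloma, KO papilloma against WT SCC and A431. RLE scaling ended the calls of Hrnr and Adamtsl3 in KO SCC against KO papilloma (adjusted p = 0.0545 each). For all of these changes the cause was not tested, nor was whether depth limits the calls. Of simulated 2-fold changes 8.42 and 9.47% were found in the mouse comparisons with 2 KO SCC libraries, 18.9% in those of 3 against 3 and 77.3% in A431.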

Other observations

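The tests of explanations weighed here were chosen only after the result was seen, except the splits of the libraries and the first form of the test of reads shared with near-identical copies. The gene groups in this and the next paragraph, their tests and the runs with 1 library left out were fixed before the data were examined. The run without genes near Dusp1 and the Y chromosome covariate were not. Immune and stromal groups that the account of WT SCC against WT skin left out also fell in the carcinomas. Dendritic and Langerhans cell genes fell in 10 of 13 and rose in 1 (10 fell and 1 rose adjusted over the list alone, adjusted p = 0.00243, and adjusted p = 0.322 with an estimated correlation), Cd207 of Langerhans cells by 6.66-fold. MHC class II genes fell in 9 of 12 and rose in 1 (10 fell and 1 rose adjusted over the list alone, adjusted p = 0.000623, and adjusted p = 0.370 with an estimated correlation), a call that ended without genes within 20 Mb of Dusp1 (adjusted p = 0.478). That window holds 6 of the 12 members, and both groups are WT. Cytotoxic lymphocyte genes fell in 8 of 14 (10 fell adjusted over the list alone, adjusted p = 0.00533, and adjusted p = 0.207 with an estimated correlation), B and plasma cell genes in 7 of 13 (8 fell adjusted over the list alone, adjusted p = 0.0383, and adjusted p = 0.322 with an estimated correlation), fibroblast and matrix genes in 12 of 18 (12 fell adjusted over the list alone, adjusted p = 0.00529, and adjusted p = 0.481 with an estimated correlation), endothelial genes in 8 of 14 with 1 higher (8 fell and 1 rose adjusted over the list alone, adjusted p = 0.0133, and adjusted p = 0.481 with an estimated correlation) and melanocyte genes in 4 of 8 (6 fell adjusted over the list alone, adjusted p = 0.0151, and adjusted p = 0.439 with an estimated correlation). The B and plasma cell list did not pass without WT skin replicate 1 or WT SCC replicate 3 (adjusted p = 0.0545 and 0.0775), nor the melanocyte list without WT skin replicate 3 (adjusted p = 0.126).

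Between carcinomas and papillomas labelled KO the lists of hair follicle, sebaceous gland, fibroblast, nerve, melanocyte, endothelium, adipocyte, MHC class II and TGF-beta target genes were also called lower (adjusted p 4.59e-05 to 0.0194, and adjusted p 0.366 to 0.566 with an estimated correlation). Over all genes tested 1 member each of the nerve and melanocyte lists passed and 0 of the other lists. Adjusted over the list alone 9 of 11 adipocyte genes fell and 1 rose, 5 of 12 of MHC class II fell and 1 rose, 3 fell of TGF-beta targets and of nerve, 1 of fibroblasts and of melanocytes, and 0 of the others. Of the 12 MHC class II members 6 lie within 20 Mb of Dusp1. The papilloma libraries differed, with mean log2 CPM of 4.68, 2.96 and -0.26 for adipocytes and 4.13, 3.01 and -0.54 for hair follicle in replicates 1, 2 and 3, against -0.20 and 1.17 and against -1.11 and 0.72 in KO SCC replicates 1 and 2. The adipocyte call ended without KO papilloma replicate 1 or 2 (adjusted p = 0.0874 and 0.282) or KO SCC replicate 1 (adjusted p = 0.0859), and that of MHC class II without genes near Dusp1 (adjusted p = 0.339). Proliferation and hypoxia were called higher, with 0 of 24 and 0 of 18 members past the threshold over all genes tested (adjusted p = 7.84e-05 and 0.0208, and adjusted p = 0.566 for each with an estimated correlation). The Y chromosome covariate ended the calls of the hair follicle and hypoxia lists (camera adjusted p = 0.162 and 0.224). With 1 library left out, the calls of MHC class II, endothelium, sebaceous gland, fibroblasts, TGF-beta targets and hypoxia also ended in at least 1 case each (adjusted p 0.0518 to 0.308). Single libraries carried some values. The platelet chemokine gene Ppbp was at 3.23 and 106 CPM in KO SCC replicates 1 and 2, and the immunoglobulin gene Ighg2c at 5.87, 24.3 and 3.96 CPM in WT SCC replicates 1, 2 and 3.

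Of genes within 20 Mb of Dusp1, a larger share was called between the genotype labels than elsewhere (odds ratio 1.51 in KO SCC against WT SCC), and the values settled no explanation. A haplotype of another strain carried along with the knockout allele may account for the excess. Its bound of 1.5, set when the approximate excess was known, was passed only just, and in KO papilloma against WT SCC the share called showed no steady fall with distance (11.7%, 3.48% and 9.47% within 5, from 5 to 10 and from 10 to 20 Mb). Neighbouring genes that change together may give such an excess anywhere. Of 12769 overlapping windows of the same width on 18 other chromosomes, each with at least 328 tested genes, 3.74% had as large a share called in KO SCC against WT SCC (0.289 to 4.27% without each chromosome in turn) and 4.95% in KO papilloma against WT SCC (0.511 to 5.64%, on both sides of the bound of 5%). These windows lay on 2 chromosomes in each contrast. Cell content stays open, since WT SCC against WT skin gave 0.807 (0.683 to 0.951), which goes against it, while KO SCC against KO papilloma gave 1.06 (0.125 to 4.0) with 2 calls near Dusp1, too few to decide. Lesion type has the same label in KO SCC and WT SCC. Reads shared with near-identical copies stay open too. Without genes that have a named pseudogene 1.49 (1.13 to 1.94) remained. The form fixed before the value was seen set this odds ratio against a bound of 1.5 and came out for shared reads, by a narrow margin. The form kept was chosen afterwards and used the interval, which lies on both sides of that bound. Leaving out named pseudogenes keeps paralogs such as the MHC and tryptase genes. Other forms of these tests, dropped after their outcomes were seen, spoke against neighbouring genes and cell content, and both for and against shared reads. Genotype itself stays open, and the contrasts share the WT SCC libraries.

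Dusp1 counts were not lower in the libraries labelled KO. A single mislabelled library could not by itself give this in all 5 of them. Such a tumour library is also argued against, since in each of the 8 tumour libraries 100% of 5 to 7 genes near Dusp1, at least 8-fold apart on the other 7, lay on the side of its label. A first form over all 11 libraries gave 23.4% at its lowest and spoke for a wrong label, but it set tumour against skin, and neither a wrong label in skin nor an exchange of all genotypes is covered. The WT libraries held Dusp1 as well (52.4 to 109 CPM), so an exchange alone would leave no group without its transcript. Transcript of a disrupted allele that is still counted could give the lowest count of 4181 in these libraries, which cannot be told apart from an intact gene because the counts do not show which exons were read.

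Markers of 11 of 15 other cell type lists were lower in KO SCC than in WT SCC, B and plasma cells by -1.11 ± 0.11 (SE, mean log2 CPM) and dendritic cells by -0.85 ± 0.24, while neutrophils differed by 0.82 ± 0.35 and endothelium by -0.20 ± 0.16. A smaller share of all other cell types in the sections may be the cause, and was taken to move the lists alike. Members with few counts shift less on this scale, as may those of cytotoxic lymphocytes, at -1.40 in KO SCC and -1.71 in WT SCC. Pairs that move apart therefore cannot by themselves exclude an equal loss. With limma over all mouse libraries 0 of 105 pairs of lists moved apart (smallest adjusted p = 0.0615), and over the 5 carcinoma libraries 11 pairs did (smallest adjusted p = 0.0302). Of 5 forms of this test 4 came out against an equal loss and the one kept left it open, so the outcome depends on the form and none of them decides. A change in B, plasma and dendritic cells themselves stays open as well. For dendritic cells the direction depends on the measure, since the summed CPM of that list was higher in KO SCC (209 and 193) than in WT SCC (158, 156 and 167).

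Groups of 3 against 3 make 10 splits, too few for a share under 0.05, so they cannot speak against chance. WT SCC against WT skin gave 9054 genes, 1 of 10 splits as many and 0 in the highest other, and 27 lists, 1 of 10 as many and 25 in the highest other. KO papilloma against WT SCC gave 1175 genes, 1 of 10 as many and 0 in the highest other, and 15 lists, 5 of 10 as many and 18 in the highest other. For the lists of that contrast the outcome went with chance, since other splits gave as many calls or more. A431 gave 8617 genes, 1 of 10 as many and 0 in the highest other, and 12 lists, 1 of 10 as many and 4 in the highest other.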
